A study of Mus musculus with 6 samples.

How the data were processed

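Liver RNA of Mdr2 knockout mice was measured by RNA sequencing in 6 libraries, 3 from mice given vehicle and 3 from mice given lycorine, an alkaloid of Amaryllidaceae plants. Per the labels' protocols, mice were 8 weeks old at the start, treatment lasted 2 weeks, liver was frozen in liquid nitrogen, total RNA was taken with a column kit and libraries were made with an Illumina RNA kit. The labels give each library a number from 1 to 3 within its group and speak of mice in the plural, without stating that each library is a separate animal. The p-values therefore measure only the spread between these libraries, which may be in part technical. Whether Mdr2 was removed in the whole body or in hepatocytes alone, sex, dose and a wild-type group are not stated in the labels used here.

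The authors deposited 1 table of expression values per gene and library. Its name speaks of FPKM, but each of the 6 columns of the deposited table sums to 1000000 within rounding, so the values are in TPM, transcripts scaled to that sum. They carry 2 decimals. The test had been planned for FPKM, and the same test was run on the TPM values. The aligner, the quantifier and the annotation are not given in the sources used here, and the submitters' processing notes list the builds GRCm38 and mm10. The columns of the lycorine libraries carry a short form of the drug's name. The columns of the vehicle libraries carry only genotype and number, so they were assigned to vehicle because no other label was left for them. TPM keeps no record of depth, so the depth of each library is unknown and no counting interval is given. No count model was used.

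The table has 58601 rows, of which 55416 carry Ensembl identifiers and 3185 are assembled loci with no gene name. Names, classes and coordinates came from GENCODE M21 on GRCm38, which holds 52083 of the identifiers and lacks 3333. Rows with a mean of at least 1 TPM over the 6 libraries were tested, which left 13854, among them 10989 protein-coding genes, 1538 assembled loci and 138 identifiers absent from M21. Values were transformed to log2(TPM + 1), so a fold change is on that scale and understates the change of weakly expressed genes. The comparison of lycorine with vehicle used limma 3.58.1 in R 4.3.3 with a variance trend, two-sided, with Benjamini-Hochberg adjustment over all tested rows and a threshold of 0.05. Genes of families with near-identical members, such as Cyp2c and Ugt2b, can share reads, and their values are uncertain.

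Gene lists, 45 in all, were written before the data were examined, as were the groups, the tests, the rule for named genes and most alternative settings. The 39 lists with at least 5 tested members were tested with limma's camera with a preset correlation of 0.01, then with an estimated correlation and with fry. Of the 828 list entries, 1 gene was not matched. A library's score for a list is the mean deviation of the list's members from their means over the 6 libraries, minus the same mean over all tested rows. Named genes were the 11 genes fixed in advance, the 10 highest and 10 lowest genes with a proper name, up to 4 members with the smallest p in each list described, and the 5 rows with the smallest p. The values of 1 gene that the rule names are not reported here. Because no gene passed, the ranked genes were taken by smallest unadjusted p on each side. The 11 fixed genes also had an exact permutation test, two-sided, over 20 assignments, for which 0.1 is the smallest possible p.

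The procedure was tested on simulated data with 13854 rows and the spread of these libraries. It recovered 1 of 50 rows changed 2-fold, 29 of 50 changed 4-fold, 48 of 50 changed 8-fold and 50 of 50 changed 16-fold, and called 8 unchanged rows. With no simulated change it called 0 rows with limma, and 687 had an unadjusted p under 0.05. The simulated rows were independent of each other, no library stood apart, and changed rows were drawn only from the more strongly expressed ones. The recovery and false calls may therefore differ for the real libraries and for weakly expressed rows. Alternatives covered the pseudocount, the filter, the scaling between libraries, the variance model, library weights, a replicate block, the set test and leaving out each library. Restricting to protein-coding nuclear genes and leaving out both libraries that stand apart were added after the data had been seen.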

Results

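Gene expression was measured in the liver of mice labelled as knockouts of Mdr2 (the gene Abcb4), the transporter that moves phosphatidylcholine into bile and whose loss causes cholestatic liver injury. Values in TPM were available for 3 vehicle and 3 lycorine libraries. The study asked how lycorine acts on cholestasis inside the liver, and its title names transketolase (Tkt) and the stress-induced transcription factor Atf3. Depth is unknown for all 6 libraries.

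The knocked-out gene was read first. Abcb4, on chromosome 5 from 8893717 to 8959231 of GRCm38, was present in all 6 libraries, at 43.5, 10.8 and 12.3 TPM in vehicle and 8.96, 8.32 and 32.2 TPM in lycorine. The labels do not state whether the gene was removed in the whole body or in hepatocytes alone. A gene-level value cannot show which part of the transcript remains, and no wild-type library was analysed here, so the genotype was not checked by this level. Transcripts of Y-linked Ddx3y were found in every library, between 3.10 and 9.41 TPM, and Xist, the X-inactivation RNA of female cells, was at 3.08 TPM in vehicle 3, 0.71 TPM in vehicle 2 and at most 0.04 TPM elsewhere.

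The libraries were unequal in makeup. Protein-coding nuclear genes made up 51.5% of TPM in vehicle 3 and 63.7% to 78.1% in the other libraries. Albumin (Alb), the main plasma protein made by hepatocytes, was at 5039 TPM in vehicle 3 and between 11824 and 19785 TPM elsewhere. Assembled loci and rows absent from M21 held 10.8% of TPM in vehicle 3, 4.11% in lycorine 3 and 1.65% to 2.93% in the other libraries. The Pearson correlation of vehicle 3 with the other libraries, across genes, averaged 0.759, against 0.855 to 0.903 for the others, and genes are not independent replicates.

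**Figure D1:**
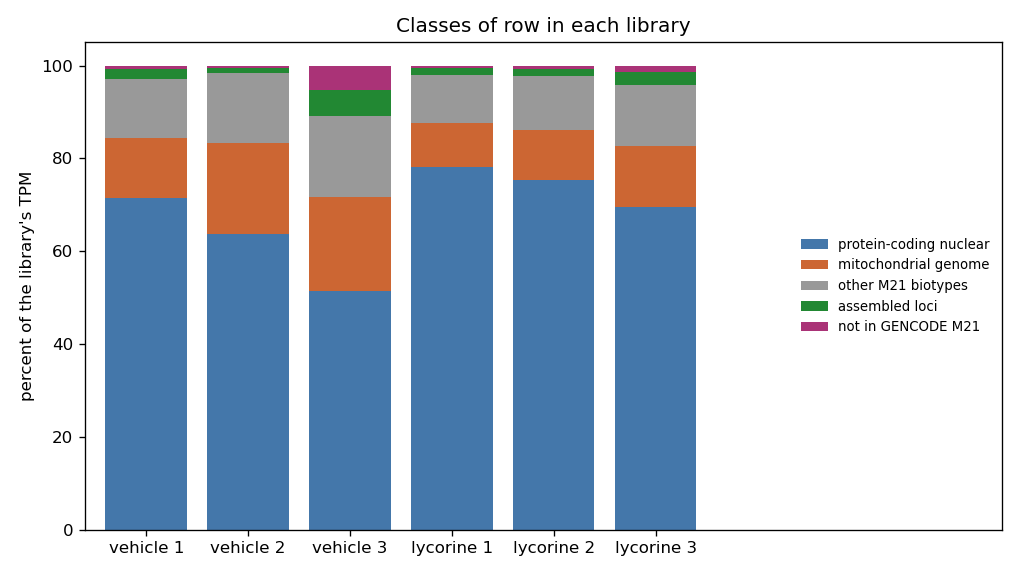
Share of each library's TPM (percent, stacked bars) by class of row, for 3 vehicle and 3 lycorine libraries. Protein-coding nuclear genes hold 51.5% in vehicle 3 and at least 63.7% in each other library.

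Among the 11 genes named in advance, Atf3 had the smallest p in limma. Atf3, on chromosome 1 from 191170296 to 191218039, was at 15.2 ± 4.61 TPM in vehicle and 3.79 ± 0.506 TPM in lycorine (SD, n = 3 each), and each lycorine library lay below each vehicle library. Its log2 fold change was -1.72 (SE 0.32), with a limma Benjamini-Hochberg adjusted p of 0.832 over all tested rows and 0.00867 adjusted over the list alone, that is those 11 genes. The exact permutation p was 0.1, the smallest possible with 3 against 3, and 0.367 adjusted over the same 11 genes. Atf3, Tkt and the lists of their pathways were fixed because the study's title names these genes. It is not known here whether that title rests on these same libraries. The p values of Atf3 adjusted over these genes or over its list may therefore not be independent of them. Tkt, an enzyme of the pentose phosphate pathway on chromosome 14 from 30548359 to 30574720, was at 57.2 ± 24.2 TPM in vehicle and 73.0 ± 12.0 TPM in lycorine (SD, n = 3 each), and the groups overlapped. Its log2 fold change was 0.44 (SE 0.40, limma adjusted p = 0.832), and it was 0.03 without vehicle 3.

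The other fixed genes were Abcb4 and 8 genes of bile acid handling. In limma 0 of the 11 passed over all rows, and 1, Atf3, passed adjusted over the list alone. Slc10a1, the main bile salt importer of hepatocytes, was at 34.2 ± 11.6 TPM in vehicle and 77.0 ± 26.1 TPM in lycorine, and Nr1h4, the bile acid receptor FXR, at 35.3 ± 0.910 and 52.1 ± 4.37 TPM (SD, n = 3 each). In both, each lycorine library's TPM lay above each vehicle library's, with log2 fold changes of 1.14 and 0.55 and an exact permutation p of 0.1. With median-of-ratios scaling these fold changes were 0.83 and 0.24. Cyp7a1, the rate-limiting enzyme of classical bile acid synthesis, was at 9.58 ± 6.19 and 18.7 ± 7.95 TPM, and Cyp8b1, which directs synthesis toward cholic acid, at 61.3 ± 27.7 and 94.99 ± 11.6 TPM, with overlapping libraries. Cyp8b1 had a log2 fold change of 0.70, and of 0.39 with median-of-ratios scaling. Nr0b2, the repressor SHP, was at 23.3 ± 15.4 TPM in vehicle and 11.3 ± 6.91 TPM in lycorine. Cyp7b1, Cyp27a1 and the bile salt exporter Abcb11 had log2 fold changes of -0.59, 0.25 and 0.03, and the latter 2 changed sign under 3 other scalings. Without vehicle 1 the values were -1.05, 0.13 and 0.52, and without vehicle 3 they were -0.32, 0.54 and -0.23. Without vehicle 1 Cyp7a1 had a log2 fold change of 0.40 in place of 1.07, and without vehicle 2 Nr0b2 had -0.41 in place of -0.89. With both vehicle 3 and lycorine 3 left out, Cyp7a1 had 1.79 and Nr0b2 -1.86.

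**Figure D2:**
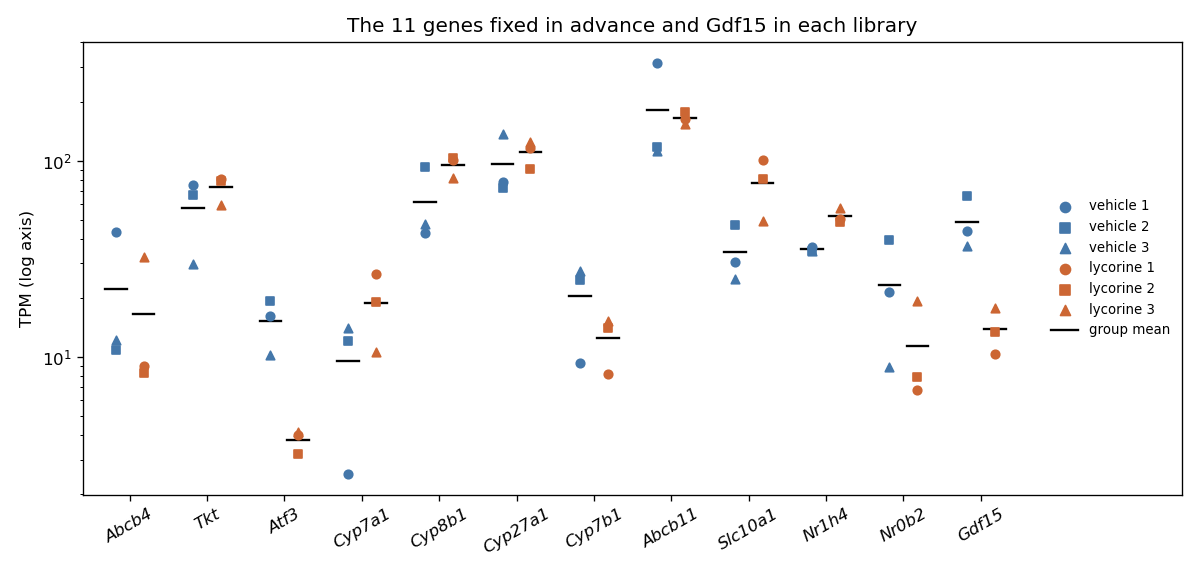
TPM (log axis) of the 11 genes fixed in advance and Gdf15 in each library, with vehicle in blue, lycorine in orange and bars at the group mean. Atf3 lies between 10.2 and 19.3 TPM in vehicle and between 3.21 and 4.14 TPM in lycorine.

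Across all genes, those with the smallest unadjusted p on the higher side included Ugt2b37, Cyp2c29 and Apoa4, and on the lower side Fcna, Atf3 and Gdf15. None of the 10 genes on either side passed the test, with limma adjusted p values of 0.450 for Ugt2b37 to 0.832. Cyp2c29, a cytochrome P450 of drug metabolism, was at 3.71 ± 2.50 TPM in vehicle and 45.5 ± 15.9 TPM in lycorine (SD, n = 3 each), a log2 fold change of 3.40 (SE 0.49). Ugt2b37, a glucuronosyltransferase, was at 8.09 ± 2.77 and 56.6 ± 13.9 TPM, and Apoa4, an apolipoprotein of lipid-rich particles, at 132.4 ± 95.6 and 957.7 ± 362.6 TPM. Cyp2c39, Cyp2c38, Dnaic1, Rnu11, Ly6k, Prlr and Ankrd55 completed the 10 with the smallest p on the higher side, with log2 fold changes of 1.45 to 4.37.

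Gdf15, a secreted stress cytokine, was at 48.7 ± 15.2 TPM in vehicle and 13.8 ± 3.69 TPM in lycorine (SD, n = 3 each), a log2 fold change of -1.73. Fcna, a ficolin made by macrophages, was at 15.5 ± 1.05 and 3.70 ± 1.44 TPM, and Vsig4, a complement receptor of Kupffer cells, at 6.05 ± 1.20 and 1.92 ± 0.234 TPM. Atf3, Maats1os, Cacna1a, Rps13-ps1, Ficd, Clec4g and Fam167b completed the 10 on the lower side, with log2 fold changes of -2.18 to -1.06. Maats1os is annotated as antisense and Rps13-ps1 as a processed pseudogene, so both can share reads with another gene.

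In limma with Benjamini-Hochberg adjustment, 0 of 13854 rows passed 0.05, and 476 had an unadjusted p under 0.05, where chance gives 692.7. Of these, 386 were higher and 90 lower in lycorine. The count was 1238 without vehicle 1, of which 1136 were higher, and 193 without lycorine 2. The split was 127 higher and 193 lower with median-of-ratios scaling, 137 and 158 with quantile normalization, and 140 and 93 with protein-coding genes alone. The median log2 fold change of all rows was 0.22 and the mean 0.14, and with median-of-ratios scaling they were -0.02 and -0.09. List means are therefore given minus the mean of all rows, and list medians minus their median. With a minimum mean of 5 TPM the median and mean of all rows were 0.32 and 0.25. Lists of strongly expressed genes are thus set against a lower baseline in the main test. Members counted as higher or lower have a log2 fold change above or below 0. For lists with a higher mean the number above the main test's median of all rows is given too. Groups did not overlap in 1470 rows, or 10.6%, where chance gives 10%. Of these 1330 were higher and 140 lower in lycorine, so under this scaling separation was mostly upward. The smallest adjusted p, 0.376 in limma, belonged to ENSMUSG00000119523, a row without a name in M21, listed at 208, 53.4 and 776 TPM in vehicle and at 0 in each lycorine library. It passed with a pseudocount of 0.1, with array quality weights and without vehicle 2, when 2 rows were called, and without lycorine 2 the 1 row called was Snord22, a small nucleolar RNA.

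Of the 39 fixed gene lists, camera with the preset correlation called 20, of which 10 were higher and 10 lower in lycorine than the other tested rows. With an estimated correlation it called 0, with a smallest adjusted p of 0.137, and fry called 0, with a smallest of 0.149. At an unadjusted p under 0.05 there were 3 lists with the estimated correlation and 6 with fry. Without vehicle 1, camera called 12. Of members of these 39 lists, 0 passed over all rows in limma, and 6 passed adjusted over the list alone.

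Kupffer cell markers, genes of the resident liver macrophages, were lower in lycorine. Of 12 tested markers 11 were lower, with a mean log2 fold change of -0.87 relative to all rows (camera adjusted p = 6.34e-08, and adjusted p = 0.137 with an estimated correlation). Clec4f, a lectin of Kupffer cells, was at 73.8 ± 22.6 TPM in vehicle and 28.7 ± 20.97 TPM in lycorine, and Cd5l, a secreted macrophage protein, at 18.1 ± 7.96 and 5.09 ± 3.25 TPM (SD, n = 3 each). Vsig4 passed limma adjusted over the list alone, and each lycorine library's list score lay below each vehicle library's score. Markers of sinusoidal endothelial cells, which line the liver's capillaries, were lower in 13 of 13 cases, with a mean of -0.69 relative to all rows (camera adjusted p = 2.39e-06, and adjusted p = 0.490 with an estimated correlation). The scores of these markers also did not overlap between groups, and such separation held for 2 of 39 lists, where chance gives 10%. Their member Clec4g was at 11.3 ± 3.60 TPM in vehicle and 4.28 ± 1.24 TPM in lycorine. Mrc1 and Kdr of that list were high in 1 vehicle library each, at 4.37, 3.39 and 35 TPM and at 14.1, 0.76 and 0.94 TPM. The endothelial scores nearest to each other between groups were 0.015 in vehicle 2 and -0.089 in lycorine 1.

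Other immune lists were lower by camera, with wide spread within groups. T and NK cell markers, 9 tested of 20 listed, had a mean of -0.63 relative to all rows (camera adjusted p = 0.000161, and adjusted p = 0.542 with an estimated correlation). That mean was -0.37 without vehicle 1, -0.39 without lycorine 3 and -0.34 with no filter. The groups overlapped in every tested member, and some were near the floor, such as Nkg7 at 2.53 ± 1.44 TPM in vehicle and 1.07 ± 0.937 TPM in lycorine. Ccl5, a T cell chemokine, was at 17.7 ± 5.83 TPM in vehicle and 8.44 ± 3.50 TPM in lycorine. Markers of monocytes and recruited macrophages had a mean of -0.37, inflammatory cytokines -0.46, MHC class II genes -0.36, and B and plasma cells -0.39. Their camera adjusted p values were 0.00393, 0.0117, 0.0248 and 0.0427, and with an estimated correlation the adjusted p values were 0.767, 0.692, 0.767 and 0.767. All 4 calls were lost without vehicle 1, which had the highest score in each, and without lycorine 3, which had the lowest. The B and plasma cell call was also lost with median-of-ratios scaling, quantile normalization, array quality weights and with both vehicle 3 and lycorine 3 left out, and the MHC class II call with no filter and with array quality weights. Without vehicle 1 the 4 means were 0.05, -0.20, 0.06 and -0.08, and without lycorine 3 they were 0.05, -0.29, 0.01 and -0.08. Without lycorine 1 the means of the monocyte, MHC class II and B and plasma cell lists were -0.79, -0.70 and -0.66, and without vehicle 3 those of the first pair were -0.66 and -0.65. Bile duct and fibrillar matrix markers, raised in many cholestatic livers, were not called (camera adjusted p = 0.605 and 0.202). Over 19 alternatives bile duct markers were called in 0, with means of -0.22 without lycorine 1 to 0.36 without vehicle 1. Fibrillar matrix markers, with a mean of -0.10, were called lower in 3, among them without lycorine 1, where the mean was -0.53, and had a mean of 0.37 without lycorine 3. Their camera adjusted p ranged from 6.98e-05 to 0.855.

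Cholesterol synthesis genes were higher in lycorine. Of 24 genes 23 were higher and 23 lay above the median of all rows, with a mean of 0.83 relative to all rows (camera adjusted p = 1.56e-09, and adjusted p = 0.540 with an estimated correlation). Fdft1, which makes squalene, was at 13.4 ± 2.32 TPM in vehicle and 33.8 ± 11.2 TPM in lycorine, and Msmo1, a later enzyme of the pathway, at 8.38 ± 2.43 and 32.4 ± 18.5 TPM (SD, n = 3 each). Insig1, a regulator of that pathway, was at 6.72 ± 3.06 and 18.9 ± 6.58 TPM. The mean was 0.50 without lycorine 2 and 1.25 without lycorine 3. Lycorine 3 had a score of -0.41 and lay within the vehicle range, while lycorine 1 and lycorine 2 were at 0.58 and 1.08.

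Of 19 bile acid synthesis genes 18 were higher and 16 lay above the median of all rows. The list's mean was 0.36 relative to all rows (camera adjusted p = 0.00503, and adjusted p = 0.490 with an estimated correlation). Akr1d1, a steroid reductase of bile acid synthesis, was at 11.01 ± 0.485 TPM in vehicle and 21.6 ± 4.43 TPM in lycorine, and Akr1c6 at 159 ± 68.4 and 316 ± 45.4 TPM (SD, n = 3 each). The call was lost with quantile normalization, with array quality weights and without vehicle 1, and the mean was 0.22 without vehicle 1, 0.62 without vehicle 2 and 0.23 without vehicle 3. Vehicle 2 had the highest score of all libraries for this list, 0.348, against 0.082 to 0.261 in lycorine. Bile acid nuclear receptor signalling was lower by camera, with a mean of -0.28 relative to all rows (adjusted p = 0.0489, and adjusted p = 0.490 with an estimated correlation), with Nr1h4 itself higher, and 4 of the 6 leave-one-out fits ended the call. Its mean was -0.13 without vehicle 2 and -0.43 without vehicle 3. The call was also lost with no filter, without the variance trend, with array quality weights and with the replicate block. It was kept in 11 of 19 alternatives. Bile acid and biliary lipid transport was not called (camera adjusted p = 0.689). In it, Slc22a7, an organic anion importer, was at 18.2 ± 9.55 TPM in vehicle and 6.41 ± 3.54 TPM in lycorine, and Abcc3, a basolateral exporter, at 32.6 ± 14.9 and 65.2 ± 18.5 TPM.

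Of 12 genes of the pentose phosphate pathway 12 were higher, but 5 of them lay below the median of all rows. The list was not called (camera adjusted p = 0.274), and its mean of 0.17 relative to all rows was -0.09 without vehicle 3. Taldo1, transaldolase, was at 84.1 ± 31.6 TPM in vehicle and 126.4 ± 26.7 TPM in lycorine (SD, n = 3 each). The ATF3 and ATF4 stress response list was not called either (camera adjusted p = 0.0746), with a median of 0.01 and a mean of -0.19 relative to all rows, which differ in sign. It was called lower in 5 of 19 alternatives, among them without vehicle 3, where its mean was -0.46, its mean was 0.02 without vehicle 1, and over the alternatives camera's adjusted p ranged from 0.000439 to 0.883. Only Atf3 and Gdf15 passed limma adjusted over the list alone, and Shmt2, a serine metabolism enzyme of the list, was at 51.0 ± 16.1 and 79.2 ± 12.0 TPM. Immediate early genes, induced within minutes of many stimuli, were lower in 13 of 15 cases, with a mean of -0.54 relative to all rows (camera adjusted p = 2.39e-06, and adjusted p = 0.540 with an estimated correlation). Their mean was -0.89 without vehicle 3, -0.35 without vehicle 1 and -0.36 without lycorine 3. In that list Fos was at 4.96 ± 1.92 and 1.81 ± 0.839 TPM and Egr1 at 15.5 ± 2.79 and 8.05 ± 3.38 TPM.

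Transcripts of the mitochondrial genome were lower in 13 of 13 cases, with a mean of -0.84 relative to all rows (camera adjusted p = 2.24e-14, and adjusted p = 0.490 with an estimated correlation). That mean was -0.51 with quantile normalization and ranged from -1.16 without vehicle 1 to -0.62 without lycorine 1 over the libraries left out. Their share of TPM was 12.9%, 19.7% and 20.1% in vehicle and 9.48%, 10.8% and 13.2% in lycorine. Nuclear genes of the respiratory chain were higher in 24 of 24 cases, and 23 lay above the median of all rows. Their mean was 0.33 relative to all rows (camera adjusted p = 0.000126, and adjusted p = 0.540 with an estimated correlation), 0.12 without vehicle 3, 0.56 without vehicle 2 and 0.19 with quantile normalization. Pericentral hepatocyte genes, expressed around the central vein, were higher in 16 of 16 cases and above the median of all rows in 15, with a mean of 0.48 relative to all rows (camera adjusted p = 0.000116, and adjusted p = 0.490 with an estimated correlation). That mean was 0.27 without vehicle 3, 0.75 without vehicle 2 and 0.21 with array quality weights. Vehicle 2 had the highest pericentral score of all libraries, 0.297, against 0.151 to 0.296 in lycorine. Among them Gulo, an enzyme of vitamin C synthesis, was at 86.3 ± 26.9 TPM in vehicle and 184 ± 35.9 TPM in lycorine (SD, n = 3 each).

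Drug metabolism genes under CAR and PXR, glycolysis, heat shock proteins and hepatocyte secreted proteins were also higher by camera, with adjusted p values of 0.0170, 0.0414, 0.0170 and 0.0177. With an estimated correlation their adjusted p values were 0.540, 0.767, 0.767 and 0.805. Without vehicle 3 all 4 lost the call, and the mean of the hepatocyte secreted proteins turned from 0.27 to -0.12 (camera adjusted p = 0.346). The drug metabolism call was also lost under 3 other scalings and without vehicle 1, where its mean of 0.52 was 0.28, and that mean was 0.87 without vehicle 2. The hepatocyte secreted call was kept in 8 of 19 alternatives and the drug metabolism call in 9 of 19. In both lists vehicle 2 had the highest score of all libraries, 0.523 and 0.437, against at most 0.312 and 0.320 in lycorine. Glycolysis and heat shock means of 0.21 and 0.38 were 0.06 and 0.14 without vehicle 3 and 0.07 and 0.22 without lycorine 1, where both calls were lost. The glycolysis call was also lost without vehicle 1, with quantile normalization, without the variance trend and with array quality weights, and was kept in 13 of 19 alternatives. The heat shock call was also lost with a minimum mean of 5 TPM and was kept in 16 of 19. Within the first list Cyp2c29 and Cyp2c54, a related P450 at 20.03 ± 5.89 and 47.8 ± 8.28 TPM, passed limma adjusted over the list alone. Ribosomal protein genes were higher in 24 of 24 cases and above the median of all rows in 22 (camera adjusted p = 0.00285, and adjusted p = 0.767 with an estimated correlation), a call lost under 3 other scalings and without lycorine 2, and their mean of 0.26 was 0.12 without vehicle 3, 0.17 without lycorine 2 and 0.40 without lycorine 3. Glycolysis had a mean of 0.35 without lycorine 3.

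**Figure D3:**
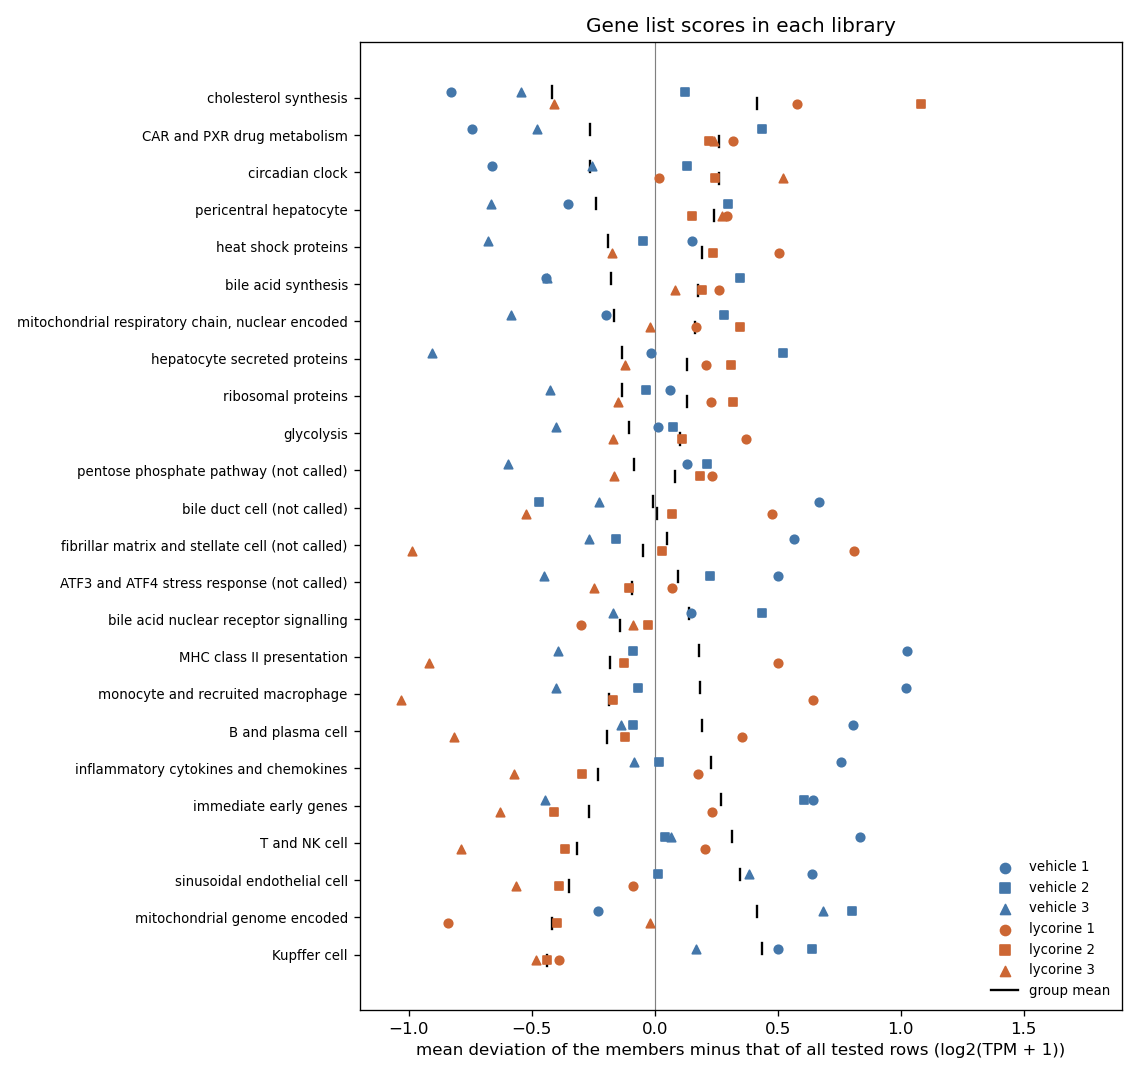
Score of each called list and 4 uncalled lists in each library (log2 scale, mean deviation of the members minus that of all tested rows), with vehicle in blue, lycorine in orange and bars at the group mean. Kupffer cell scores lie between 0.17 and 0.64 in vehicle and between -0.48 and -0.39 in lycorine.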

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

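The restriction to protein-coding genes, the fits without both libraries that stand apart, and the set tests without vehicle 3 were chosen after the data had been seen. Rows past adjusted p 0.05 in limma numbered 0, and 1 with a pseudocount of 0.1 and 1 with array quality weights, each lower and over 2-fold, and that row was ENSMUSG00000119523. Leaving out each library gave 0 to 2 such rows, all lower and over 2-fold, ENSMUSG00000119523 and ENSMUSG00000119844 without vehicle 2, and Snord22 without lycorine 2; the cause was not tested. The number of gene lists called by camera ranged from 12 without vehicle 1 to 21 without vehicle 2. It was 0 with an estimated correlation and 0 with fry, and again 0 with each when vehicle 3 was left out. Fry called 1 list with array quality weights and 1 with protein-coding genes alone, and its mixed test called 0 in the chosen setting, 6 without vehicle 3, 7 with no filter and 6 with array quality weights. Without vehicle 3 the hepatocyte secreted proteins turned from 0.27 to -0.12 relative to all rows and were not called, within a range of -0.12 to 0.59 over the libraries left out, and that library has the lowest score for that list, -0.91. Lists called in each alternative that tested them with camera's preset correlation were cholesterol synthesis, immediate early genes, Kupffer cell, mitochondrial genome, nuclear respiratory chain, pericentral hepatocyte, sinusoidal endothelial cell, and T and NK cell markers. These alternatives all kept the preset of 0.01, so the repeated calls do not test it. The estimated correlation was -0.06 for Kupffer cell markers and 0.16 to 0.69 for the others. Of these lists, only Kupffer cell and sinusoidal endothelial cell had scores that did not overlap between groups. Atf3 kept its direction in 19 of 19 alternatives, from -2.03 to -1.54, with limma adjusted p from 0.284 to 1, and Tkt ranged from 0.03 to 0.68. With the number as a replicate block, limma called 0 rows, 1033 had an unadjusted p under 0.05, camera called 18 lists, and fry's mixed test called 13. There the camera calls of bile acid nuclear receptor signalling and of CAR and PXR drug metabolism were lost. Deviations of same-numbered libraries correlated at 0.31, 0.05 and 0.29 across genes. Those of differently numbered libraries were negative, down to -0.34, except vehicle 2 with lycorine 1, at 0.21. Each group was centred on its own mean, so positive values in some pairs force negative ones in others. The negative values are therefore no separate sign of a link. The labels do not state that the numbers pair the libraries, so the main test took no pairing. A link between same-numbered libraries stays open. Rescaling each library to the same sum changed no call, since the values already share it. Depth is unknown, so its effect on weakly expressed rows cannot be given.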

Other observations

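The tests of correlation among protein-coding genes, of transcript length and of other splits of the libraries were set before their results were seen, and the other tests here were chosen after.

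Genes of the circadian clock were higher in lycorine in 15 of 16 cases and above the median of all rows in 15, with a mean of 0.52 relative to all rows (camera adjusted p = 0.000390, and adjusted p = 0.490 with an estimated correlation). Dbp, a clock output transcription factor, was at 95.8 ± 38.7 TPM in vehicle and 248 ± 44.2 TPM in lycorine (SD, n = 3 each). Per3, a clock repressor, was at 1.93 ± 0.538 and 4.52 ± 0.875 TPM, and Tef, related to Dbp, at 17.7 ± 7.29 and 31.0 ± 4.03 TPM. The call was lost without vehicle 1, where the mean was 0.32, and without lycorine 3. The time of day of tissue collection is not in the labels.

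Neutrophil genes had only 4 tested members and were not tested as a list. S100a9, a neutrophil calcium-binding protein, was at 12.7, 3.80 and 3.34 TPM in vehicle and 0.550, 1.55 and 1.20 TPM in lycorine. Its limma adjusted p was 0.0454 over those 4 genes alone and 0.832 over all rows. The adipose, gallbladder and intestine, pancreas, skeletal muscle and sex chromosome lists had 4, 3, 3, 2 and 3 tested members. The remaining tested lists were not called by camera, with adjusted p values from 0.0639 for gluconeogenesis to 0.689 for female-biased liver genes. Over 19 alternatives male-biased liver genes were called lower in 7, with adjusted p values of 0.00116 to 0.900 and means of -0.61 without vehicle 1 to 0.13 without vehicle 2. Gluconeogenesis was called higher in 5 (adjusted p 0.00364 to 0.523) and acute phase proteins lower in 4 (adjusted p 0.000684 to 0.957, means -0.47 to 0.13). Ribosome biogenesis was called in 2, and endoplasmic reticulum chaperones, fatty acid synthesis and NRF2 targets in 1 each.

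Vehicle 3 stood apart from the other libraries. Among protein-coding nuclear genes rescaled to the same sum, its mean Pearson correlation with the others across genes was 0.824. The next lowest library was at 0.905. Rows of the other classes alone therefore do not account for the distance. Transcript outside messenger RNA that is counted within protein-coding genes stays in this comparison, so it cannot decide on that cause. Cmss1, Gphn and ENSMUSG00000119584 were at 19543, 19012 and 23822 TPM in vehicle 3 and at most 6955, 6863 and 7346 TPM elsewhere. Marker means of 13 other cell types and tissues were compared between vehicle 3 and the highest other library. The largest excess was 0.343 on the log2 scale, for 3 pancreas genes. Of these, Zg16 was at 7.97 TPM in vehicle 3 and at most 0.09 TPM elsewhere. This argues against a large admixture of those types. A smaller one stays open, since values were not rescaled for vehicle 3's low protein-coding share and some lists had few members. A transcript length bias stays open, with a Spearman correlation across genes of 0.291 between length and that library's deviation, against -0.244 to 0.037 in the others. No biological explanation was tested, since the labels name none within a group.

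Atf3 and Gdf15 were lower in each lycorine library than in each vehicle library. The value nearest to 0 of the pair was -1.82 over 3 other scalings. Those scalings lowered the mean of all tested rows, 0.14 in the main test, so a move away from 0 was bound to follow. They show only that the main scaling did not produce the fall. Without vehicle 3 the value nearest to 0 was -1.91, which decides nothing, since that library was the lowest of vehicle for both genes. The other 17 tested members of the ATF3 and ATF4 list had a median log2 fold change, not relative to all rows, of 0.253. It was -0.00026 without vehicle 3 (quartiles -0.30 and 0.16). Relative to all rows these medians were 0.03 and -0.19. The values argue against a fall of the whole list by as much as the pair and leave a smaller one open. Gdf15 was picked by its small p in these data, so the pair lying below the other members was partly fixed by that choice. Handling of the tissue before freezing may contribute: the mean of the immediate early genes relative to all rows was -0.537, but their scores overlapped between groups. That explanation and an effect of lycorine, untested by these data, cannot be told apart.

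Of the 12 tested Kupffer cell markers, 5 were lower and 1 was higher in each lycorine library than in each vehicle library, and the others overlapped. The list score of all 12 markers was lower in each lycorine library. Their mean log2 fold change, not relative to all rows, was -0.74, and the value nearest to 0 over 3 other scalings was -0.930. Those scalings lowered the mean of all tested rows from 0.14 to 0.00066 or lower, so a move away from 0 was bound to follow. They show only that the main scaling, with all rows shifted upward, did not produce the fall. Relative to all rows the list mean was -1.01 without vehicle 3, which decides nothing, since that library had the lowest vehicle score. A larger hepatocyte share could dilute all other cell types. The Kupffer score minus the mean of the bile duct and stellate scores differed by -0.833 (SE 0.488) between lycorine and vehicle, with overlapping libraries, so dilution and a change in Kupffer cells cannot be told apart. An effect of lycorine on these cells stays open and untested.

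The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 476 rows at an unadjusted p under 0.05, and 6 of 10 splits gave as many, the highest other 1763. It gave 20 lists by camera, with 19 as the highest other, so 1 split of 10 gave as many. It gave 0 rows past adjusted p in limma, so that 10 of 10 splits give as many by construction, with 10 rows as the highest other. The split with 1763 rows set vehicle 1 with lycorine 1 and lycorine 2 against the rest, and 1 row passed adjusted p in it.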
